A study of Arabidopsis with 12 samples.

How the data were processed

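RNA sequencing of Arabidopsis thaliana seedlings was analysed from the deposited tables alone, since no reads were used. There were 12 libraries: wild type (Col-0) and pad4, each with Fe (+Fe) and without Fe (-Fe) for 7 d, with 3 libraries per group. Per the labels, the tissue is the shoot in a sample field, leaves and roots in the protocol and seedlings in the design text, and this disagreement was left as it stands.

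The expression table holds FPKM (fragments per length of the gene and per mapped fragments) for 28693 loci, computed by the authors before they deposited it, on TAIR10 per the submitters' processing notes. The aligner, the counting tool and their versions are not given in the sources used here. Of the loci, 354 merge more than 1 gene and 630 have no gene name. A 2nd copy of the table differs by at most 0.005 FPKM and was used only for that check. In 4 further deposited tables the authors compared 2 groups each, with a group FPKM scaled within that table. The log2 fold, the p-value and the q-value of those tables are the authors', per the file headers. A test score of the authors, per the file headers, was not used. The smallest deposited p-value is 5e-05.

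The planned test for counts was not used, since the files hold FPKM, and the test planned for normalized values took its place. Loci at 1 FPKM or more in at least 3 libraries (20173) were tested with limma 3.58.1 in R 4.3.3 (eBayes with trend) on log2(FPKM + 1). All 12 libraries stood in 1 fit with 1 mean per group, and calls required a Benjamini-Hochberg adjusted p under 0.05. The added 1 understates the change of low genes, and FPKM of 1 library depend on each other through the total. The highest locus held 13.7 ± 0.2% of the FPKM in wild-type +Fe libraries, 5 ± 1.2% in wild-type -Fe, 11 ± 3.4% in pad4 +Fe and 4.3 ± 1.7% in pad4 -Fe. No library sizes were given, so depth is known only relative to a library (0.57 to 1.00) and no counting intervals were computed. A value of 0 in this table can be a failed estimate: 105 loci stood at 0 in 1 library and at 5 FPKM or more in another of the same group. Genes are therefore said to be listed at 0, and no fold is given against a group at 0.

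The 5 contrasts were the Fe effect in the wild type, the Fe effect in pad4, the genotype effect at +Fe, the genotype effect at -Fe, and the interaction, which is the Fe effect in pad4 minus that in the wild type. Fe effects are libraries labelled -Fe over libraries labelled +Fe, and genotype effects are pad4 over wild type. The labels were checked on PAD4 and on Fe-status genes before any effect was read.

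Groups, contrasts, gene lists and the rule for the named genes were fixed before the data were examined. The 19 lists hold genes of Fe acquisition, Fe-deficiency regulation and redistribution, Fe storage, superoxide dismutases with Cu and Zn homeostasis, salicylic acid, jasmonate, ethylene, auxin, cytokinin, gibberellin, abscisic acid, photosynthesis, root markers, heat shock, touch and wounding, the circadian clock, phosphate starvation, phenylpropanoids with anthocyanin, and camalexin with pathogen-induced defence. Each was tested with camera (limma) at a preset inter-gene correlation of 0.01 over the 95 combinations of list and contrast, with an estimated correlation and with fry beside it. Member counts come from the test of single genes, and are also given adjusted over the list alone.

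Named genes follow a rule with 3 parts. Part 1 takes, per contrast, the 6 largest rises and the 6 largest falls among called genes that have a symbol, a mean of at least 5 FPKM in the higher group and no overlap of replicates (no overlap condition for the interaction). Part 2 takes up to 3 called members of each list with the smallest adjusted p, or the highest member where none was called; members of lists that are only counted are left out. Part 3 takes PAD4, EDS1, ICS1, PR1, NPR1, IRT1, FRO2, FIT, bHLH38, bHLH39, bHLH100, bHLH101, BTS and FER1.

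Alternatives tried were no low-value filter, quantile normalization, limma without the trend, a pseudocount of 0.1, the replicate number as a block, only the compared groups in the fit, a threshold of 1 log2 unit, and leaving out each library in turn. Fits without the 4 libraries that stand apart, and without the 105 loci with a 0 beside a high value, were added after the data were seen. The labels give replicate numbers but no pairing, so pairing was checked on the data. Deviations of same-numbered libraries correlated at 0.12 to 0.51 between wild-type +Fe, wild-type -Fe and pad4 +Fe libraries, every pair over 0.1, and at -0.42 to 0.14 in pairs with pad4 -Fe. Libraries 1 and 3 also correlated across numbers between the wild-type groups (0.29 and 0.23). Wild-type -Fe library 3 and pad4 +Fe library 1 correlated at 0.23, above the lowest same-numbered value of 0.18 between these groups. Only 4 of the 12 libraries correlated best with their own number, so pairing by number is not shown. A fit with the replicate number as a block in the 9 libraries without pad4 -Fe was added as an alternative, also after the data were seen. The test was checked on simulated data for the Fe effect in the wild type over 20173 loci. It called 38, 90 and 98% of loci changed by 0.5, 1 and 2 log2 units, 88% of those changed by -1, and 7 unchanged loci. Each size was given to 50 loci, with noise drawn independently per locus. The real data held far more called loci and 4 libraries with a shared deviation, so these shares need not hold for them. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.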

Results

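Seedlings of Arabidopsis thaliana were profiled by RNA sequencing to ask how salicylic acid signalling relates to the response to Fe deficiency. The wild type was the Col-0 accession, and the mutant was pad4, mutated in PAD4, a lipase-like protein that acts with EDS1 upstream of salicylic acid accumulation. Seedlings were placed on complete solid medium (+Fe) or on the same medium without Fe (-Fe) for 7 d, at 24 °C, under 140 µmol photons per m2 and s and a 16 h day and 8 h night. The 2 genotypes and 2 Fe supplies gave 4 groups of 3 libraries, 12 in all. Expression was given as FPKM for 28693 loci, of which 20173 reached 1 FPKM in at least 3 libraries and were tested. The FPKM of a library summed to between 894824 and 1004002, and 19096 to 19311 loci lay at 1 FPKM or more. Relative depth, read from the lowest values above 0, ranged from 0.57 to 1.00 of that of wild-type +Fe replicate 1, and the absolute depth is unknown. Replicates of a group correlated across loci at r = 0.980 to 0.992 (loci are not independent replicates). Values below are means ± SD over the 3 libraries of a group, and fold changes are on the log2(FPKM + 1) scale.

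The genotype labels were checked on the mutated gene. PAD4 (AT3G52430, TAIR10 chromosome 3, 19431371 to 19434403) lay between 18.1 and 22.0 FPKM in the 6 wild-type libraries and between 10.3 and 13.6 FPKM in the 6 pad4 libraries, with no overlap. Its log2 difference between pad4 and wild type was -0.70 (SE 0.09, limma adjusted p = 0.00102) in libraries labelled +Fe and -0.77 (SE 0.09, adjusted p = 0.000108) in libraries labelled -Fe. Transcript of the mutated gene was lower but still measured.

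The Fe labels were checked on genes whose response to Fe is textbook knowledge, and the 7 genes checked went against the labels in all 12 libraries, whereas FIT, given below, ran with them. bHLH100 (AT2G41240, chromosome 2, 17198282 to 17199320), a transcription factor induced when Fe is short, lay between 976 and 1137 FPKM in the 6 libraries labelled +Fe and between 0.122 and 0.666 FPKM in the 6 labelled -Fe. IMA1 (AT1G47400, chromosome 1, 17385717 to 17386186), a peptide gene that promotes Fe uptake, lay between 536 and 753 FPKM in libraries labelled +Fe and between 1.88 and 5.50 FPKM in those labelled -Fe. FER1 (AT5G01600, chromosome 5, 227953 to 230051), a ferritin gene that is raised by Fe, lay between 10.3 and 11.8 FPKM in libraries labelled +Fe and between 271 and 333 FPKM in those labelled -Fe. For this reason the groups are called libraries labelled +Fe and libraries labelled -Fe throughout, and every direction of an Fe effect below is a direction between labels. "At +Fe" and "at -Fe" below likewise mean in libraries so labelled.

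The labels also differ on the tissue: a sample field names the shoot, the protocol names leaves and roots, and the design text names whole seedlings. Of 19 root marker genes, 5 averaged 1 FPKM or more, with a list median of 0.16 FPKM. The highest was SCR, at 19.6 FPKM, while the median of 27 photosynthesis genes was 750.0 FPKM.

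The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these samples. The Fe label accounted for most of the variation: component 1 held 64.5% of the variance and separated the labels, and component 2 held 13.6% and separated the genotypes, further apart in libraries labelled -Fe. Within each group, 1 library (wild-type +Fe 2, wild-type -Fe 2, pad4 +Fe 2 and pad4 -Fe 3) deviated from its group along a shared axis, with pairwise correlations of deviations from 0.41 to 0.51 across loci.

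**Figure D1:**
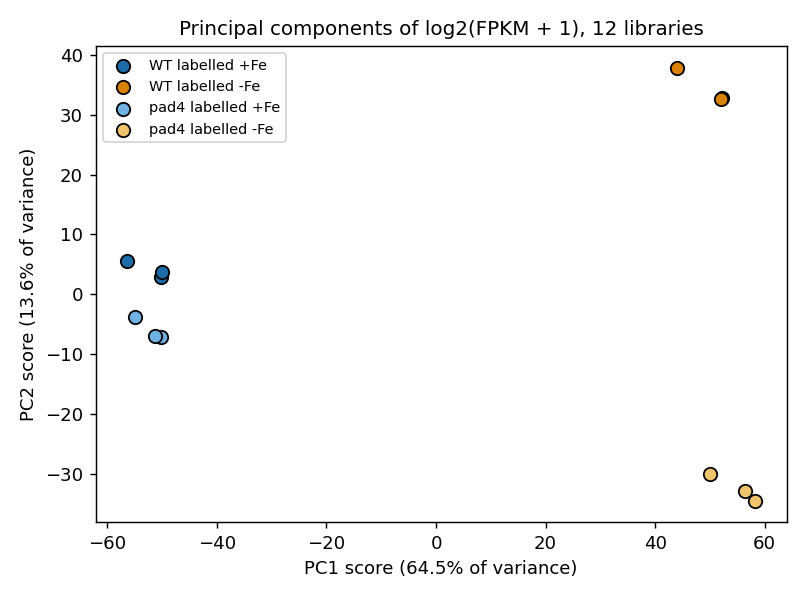
Scores of the 12 libraries on the principal components 1 (horizontal, 64.5% of variance) and 2 (vertical, 13.6%) of log2(FPKM + 1). Each point is 1 library, coloured by group. Libraries labelled +Fe lie between -56.37 and -50.00 on component 1, and libraries labelled -Fe between 44.04 and 58.24.

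**Figure D2:**
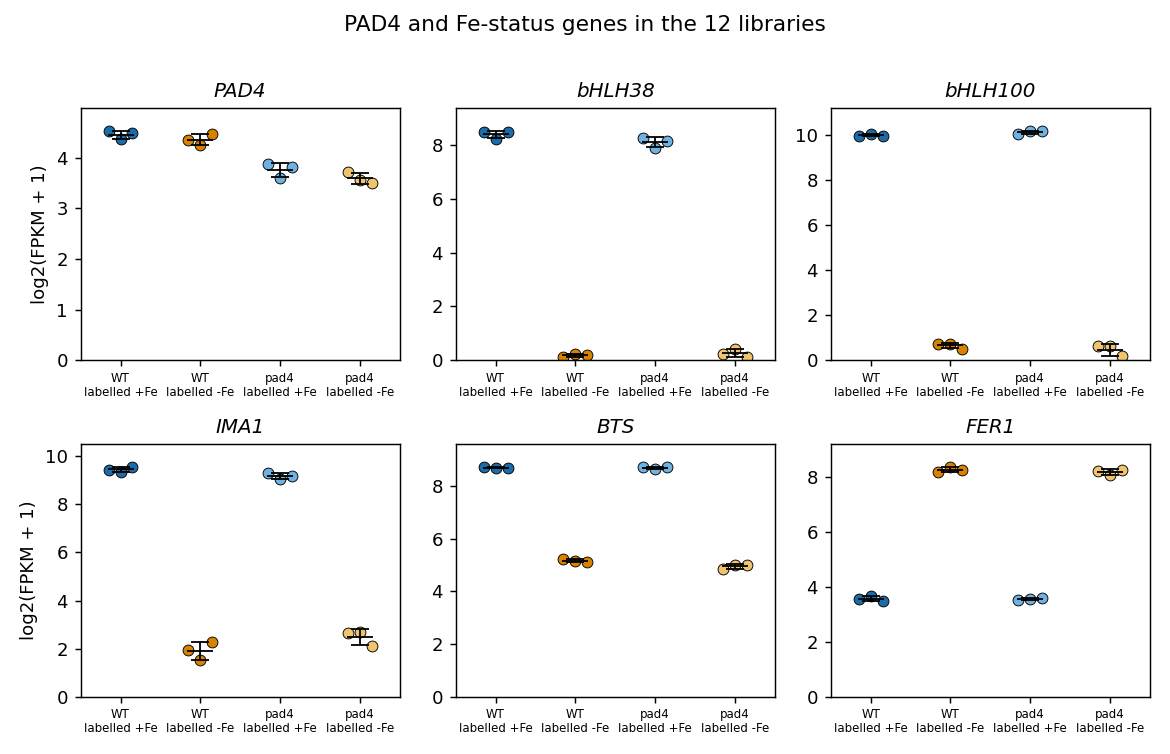
Log2(FPKM + 1) of PAD4 and 5 Fe-status genes (vertical axes, from 0) in the 4 groups. Points are libraries and bars give the mean and SD (n = 3). bHLH38, bHLH100, IMA1 and BTS are high in the libraries labelled +Fe, FER1 is high in those labelled -Fe, and PAD4 is lower in both pad4 groups.

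The largest named falls under the Fe label in the wild type were those of Fe-status genes. The largest named rises were those of heat shock genes, given below. bHLH100 was lower in libraries labelled -Fe (0.578 ± 0.137 FPKM) than in those labelled +Fe (997 ± 31.3 FPKM), a log2 difference of -9.31 (SE 0.12, limma adjusted p = 1.08e-12). The related bHLH38 (AT3G56970), bHLH39 (AT3G56980) and bHLH101 (AT5G04150) fell from 338 ± 33.3, 309.9 ± 22.5 and 145 ± 4.96 FPKM to at most 0.216 FPKM, with log2 differences of -8.22, -8.20 and -6.92. bHLH38 and bHLH39 are similar neighbours that the files place in 1 locus span (chromosome 3, 21046341 to 21087957), so reads can have been shared between them. IMA1 and its near-copy IMA2 (AT1G47395) fell by 7.56 and 7.42 log2 units. Among genes that met the naming rule, the largest rises outside the heat shock genes were those of NEET (AT5G51720), which encodes an Fe-S cluster protein, from 0.0669 ± 0.116 to 73.6 ± 2.34 FPKM, and of the ferritin gene FER4 (AT2G40300), from 0.614 ± 0.293 to 67.4 ± 8.36 FPKM.

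Among regulators of Fe deficiency and Fe redistribution, 2 of 29 tested members were called higher and 21 lower (23 called adjusted over the list alone), with a list median of -3.03 log2 units (camera adjusted p = 6.68e-11). BTS (AT3G18290), an Fe-binding ubiquitin ligase, fell from 411 ± 5.42 to 34.8 ± 1.3 FPKM, with a log2 difference of -3.53. In the Fe storage list, 8 of 8 tested members were called higher and 0 lower (8 called adjusted over the list alone), with a median of 2.24 (camera adjusted p = 4.04e-07). FER1 rose from 10.97 ± 0.774 to 311 ± 19.6 FPKM. Of the root Fe acquisition genes, 2 of 10 tested members were called higher and 6 lower (8 called adjusted over the list alone), with a median of -1.24 (camera adjusted p = 0.0062); with an estimated correlation the adjusted p was 0.0959. That median includes IRT1, whose fitted value depends on the added 1. MYB72 (AT1G56160), FRO2 (AT1G01580, a ferric chelate reductase) and FRD3 (AT3G08040, a citrate transporter) had log2 differences of -4.16, -3.34 and -2.48. IRT1 (AT4G19690), the main root Fe transporter, stood at 5.76 ± 0.419 FPKM in libraries labelled +Fe and was listed at 0 in the 3 wild-type libraries labelled -Fe. FIT (AT2G28160), the regulator of root Fe uptake, went the other way, from 0.885 ± 0.377 to 3.28 ± 0.137 FPKM (log2 difference 1.2, adjusted p = 7.71e-05). The list of superoxide dismutases and Cu and Zn genes was split, as 6 of 14 tested members were called higher and 8 lower (14 called adjusted over the list alone). The copper chaperone gene CCS (AT1G12520) rose by 2.76 log2 units, while the zinc transporter gene ZIP4 (AT1G10970) and the copper chaperone gene CCH (AT3G56240) had differences of -2.74 and -1.68. Its median was -0.94 and its mean 0.00 (camera adjusted p = 0.509).

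Hormone lists moved in the wild type as well. Of the salicylic acid genes, 23 of 33 tested members were called higher and 5 lower (28 called adjusted over the list alone), with a median of 0.81 in libraries labelled -Fe (camera adjusted p = 3.52e-05). DMR6 (AT5G24530), a salicylic acid hydroxylase, rose from 72.6 ± 1.54 to 208 ± 5.52 FPKM, NIMIN2 (AT3G25882), an NPR1-interacting protein, from 14.99 ± 1.09 to 51.5 ± 3.78 FPKM, and FMO1 (AT1G19250), an enzyme of systemic immunity, from 3.99 ± 0.431 to 15.1 ± 1.04 FPKM. PR1 (AT2G14610, chromosome 2, 6241704 to 6242463), the classical salicylic acid marker, rose from 80.5 ± 9.75 to 279.9 ± 48.6 FPKM (log2 difference 1.78, SE 0.14, adjusted p = 1.1e-06), and ICS1 (AT1G74710), the synthesis enzyme, by 0.38 log2 units (adjusted p = 0.00363). EDS1 (AT3G48090) and NPR1 (AT1G64280) did not pass the test (log2 differences 0.20 and -0.30, adjusted p = 0.114 and 0.108), though NPR1 did without wild-type -Fe replicate 2 (log2 difference -0.43) or the 4 libraries that stand apart (-0.31), and EDS1 did after quantile normalization (0.29). Both did with the replicate number as a block in the 9 libraries other than pad4 -Fe (0.20 for EDS1 and -0.30 for NPR1). Of the jasmonate genes, 2 of 27 tested members were called higher and 23 lower (26 called adjusted over the list alone), with a median of -0.86 (camera adjusted p = 4.28e-06, 0.0582 with an estimated correlation). The synthesis genes LOX4 (AT1G72520) and AOS (AT5G42650) had differences of -1.70 and -1.46, and the chitinase gene CHIB (AT3G12500) rose by 3.13. In the auxin list, 15 of 20 tested members were called higher and 2 lower (18 called adjusted over the list alone), with a median of 0.81 (camera adjusted p = 0.000553). The auxin transporter gene PIN3 (AT1G70940) and the conjugating enzyme gene GH3.3 (AT2G23170) rose by 1.3 and 0.93, while GH3.6 (AT5G54510) had a difference of -1.19. In the abscisic acid list, 1 of 16 tested members were called higher and 8 lower (9 called adjusted over the list alone, median -0.23, camera adjusted p = 0.041, 0.102 with an estimated correlation). That call ended without wild-type +Fe replicate 2 (adjusted p = 0.0575), wild-type +Fe replicate 3 (0.053) or wild-type -Fe replicate 3 (0.0609).

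Photosynthesis genes were higher in wild-type libraries labelled -Fe: 24 of 27 tested members were called higher and 0 lower (24 called adjusted over the list alone), with a median of 0.88 (camera adjusted p = 6.68e-11, 0.0521 with an estimated correlation). HEMA1 (AT1G58290), an enzyme of chlorophyll precursor synthesis, rose from 9.24 ± 0.136 to 149 ± 4.69 FPKM, the ferredoxin gene FD2 (AT1G60950) by 2.47 and the photosystem I gene PSAF (AT1G31330) by 1.98 log2 units. Phenylpropanoid and anthocyanin genes were lower, as 1 of 17 tested members were called higher and 14 lower (15 called adjusted over the list alone, median -1.23, camera adjusted p = 6.97e-07, 0.0521 with an estimated correlation). DFR (AT5G42800), UF3GT (AT5G54060) and F3H (AT3G51240) of the flavonoid pathway had differences of -3.02, -2.77 and -1.78. In the phosphate starvation list 7 of 7 tested members were called higher and 0 lower (7 called adjusted over the list alone, median 1.03, camera adjusted p = 0.000245, 0.0528 with an estimated correlation), with SPX1 (AT5G20150), the transporter gene PHT1;4 (AT2G38940) and the lipid synthase gene MGD2 (AT5G20410) up by 2.08, 1.38 and 0.57. Of the 6 lists without a call, the camera adjusted p ranged from 0.0807 to 0.524: these held the ethylene (median -0.63), cytokinin (0.40), gibberellin (0.23), camalexin (-0.24) and root marker (-0.40) genes besides the superoxide dismutase list.

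Lists chosen as signs of handling moved with the Fe label too. In the heat shock list 10 of 10 tested members were called higher and 0 lower (10 called adjusted over the list alone, median 4.23, camera adjusted p = 2.71e-09, 0.0879 with an estimated correlation). The small heat shock protein genes ATHSP22.0 (AT4G10250), HSP18.2 (AT5G59720), HSP21 (AT4G27670) and HSP17.6C (AT1G53540) rose by 7.61, 6.98, 6.52 and 5.77 log2 units, HSP17.6C from 29.6 ± 2.98 to 1667 ± 177 FPKM. In the touch and wounding list 0 of 7 tested members were called higher and 5 lower (6 called adjusted over the list alone, median -1.85, camera adjusted p = 0.00142). The early stress regulators ZAT12 (AT5G59820), WRKY33 (AT2G38470) and ZAT10 (AT1G27730) had differences of -3.13, -2.01 and -1.85. In the circadian clock list 1 of 12 tested members were called higher and 8 lower (9 called adjusted over the list alone, median -0.58, camera adjusted p = 0.00204), with PRR9 (AT2G46790), RVE1 (AT5G17300) and ELF4 (AT2G40080) at -1.94, -1.43 and -1.08. In all, limma called 10475 loci in the wild type, 5082 higher and 5393 lower in libraries labelled -Fe. After quantile normalization the larger side turned (5613 higher and 5015 lower), so it depends on the scaling. Of the 10475, 2364 differed by at least 1 log2 unit, 1074 higher and 1290 lower.

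In pad4, the Fe label moved the same Fe-status genes. bHLH100 fell from 1105 ± 53.9 to 0.403 ± 0.244 FPKM (log2 difference -9.64, SE 0.12, limma adjusted p = 7.49e-13), and bHLH39, bHLH38 and bHLH101 had differences of -8.04, -7.86 and -7.19. IMA2 and IMA1 had differences of -7.01 and -6.69, and BTS of -3.73. NEET rose from 0.142 ± 0.123 to 90.9 ± 9.91 FPKM, FER4 from 0.286 ± 0.0268 to 60.3 ± 11.5 FPKM and FER1 from 10.9 ± 0.308 to 294 ± 20.7 FPKM. The chloroplast genes ENH1 (AT5G17170, a rubredoxin-like protein) and SAPX (AT4G08390, a stromal ascorbate peroxidase) rose by 5.22 and 5.05 log2 units. Among the Fe-deficiency regulators 4 of 29 tested members were called higher and 22 lower (26 called adjusted over the list alone, median -2.85, camera adjusted p = 3.87e-08). In the Fe storage list 8 of 8 tested members were called higher and 0 lower (8 called adjusted over the list alone, median 2.52, camera adjusted p = 3.55e-07), and in the Fe acquisition list 2 of 10 tested members were called higher and 6 lower (8 called adjusted over the list alone, median -1.12, camera adjusted p = 0.00485, 0.0879 with an estimated correlation). MYB72, FRO2 and FRD3 had differences of -3.77, -3.54 and -2.03. IRT1 stood at 4.61 ± 0.597 FPKM in pad4 libraries labelled +Fe and at 0, 0.0682 and 0.0533 FPKM in those labelled -Fe. FIT had a difference of 0.54 (adjusted p = 0.0133), and its call ended without pad4 +Fe replicate 3 (log2 difference 0.45) or pad4 -Fe replicate 1 (0.43). The Cu and Zn list was again split, with CSD2 (AT2G28190, a chloroplast superoxide dismutase), CCS and ZIP4 at 4.81, 2.91 and -2.73.

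The hormone lists were tested in pad4 in the same way, and their difference from the wild type is given below as the interaction. In the salicylic acid list 15 of 33 tested members were called higher and 9 lower (24 called adjusted over the list alone), and the list was not called (median 0.15, camera adjusted p = 0.137). PCC1 (AT3G22231) and EDS1B (AT3G48080) rose by 2.08 and 1.16, while UGT76B1 (AT3G11340), a glucosyltransferase that acts on immune regulators, had a difference of -2.13. PR1 went from 97.3 ± 14.3 to 69.8 ± 5.04 FPKM (log2 difference -0.47, adjusted p = 0.0143), and this call ended without pad4 +Fe replicate 2 (log2 difference -0.36) or pad4 -Fe replicate 2 (-0.42). EDS1 and NPR1 had differences of -0.40 and -0.58 (adjusted p = 0.00566 and 0.00552). ICS1 had a difference of -0.29 (adjusted p = 0.016), which lost its call without pad4 +Fe replicate 2 (log2 difference -0.25) or when only these 2 groups were fitted (-0.29). The jasmonate list was not called (camera adjusted p = 0.12, but 0.0438 and lower without the low-value filter): 6 of 27 tested members were called higher and 16 lower (22 called adjusted over the list alone), the median was -0.59 and the mean 0.30. Its defence genes PR4 (AT3G04720) and CHIB rose by 2.55 and 4.13, the defensin gene PDF1.3 (AT2G26010) from 4.56 ± 1.45 to 209 ± 80.7 FPKM, and the synthesis gene LOX2 (AT3G45140) had a difference of -1.27. In the abscisic acid list 1 of 16 tested members were called higher and 13 lower (15 called adjusted over the list alone, median -1.45, camera adjusted p = 1.79e-06). NCED3 (AT3G14440), the key enzyme of abscisic acid synthesis, fell from 32.6 ± 0.725 to 5.49 ± 0.977 FPKM, and COR15A (AT2G42540, a cold-regulated protein) and ABI2 (AT5G57050, a phosphatase of the pathway) had differences of -2.27 and -1.61.

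Photosynthesis genes were higher in pad4 libraries labelled -Fe, as 24 of 27 tested members were called higher and 0 lower (24 called adjusted over the list alone, median 1.08, 0.75 after quantile normalization, camera adjusted p = 9.72e-11, 0.0521 with an estimated correlation). HEMA1, FD2 and PSAF rose by 4.13, 2.63 and 2.1. Among the phenylpropanoid genes 0 of 17 tested members were called higher and 15 lower (15 called adjusted over the list alone, median -1.18, camera adjusted p = 1.37e-06, 0.0528 with an estimated correlation), with the anthocyanin genes DFR, PAP1 (AT1G56650) and TT19 (AT5G17220) at -2.35, -2.73 and -2.97. Among the heat shock genes 0 of 10 tested members were called higher and 8 lower (8 called adjusted over the list alone, median -1.3, camera adjusted p = 0.000251, 0.294 with an estimated correlation), with HSP23.6 (AT4G25200), HSP17.4 (AT3G46230) and HSP17.6II (AT5G12020) at -4.07, -2.26 and -1.63. The touch list (median -1.17, camera adjusted p = 0.0148, 0.0685 with an estimated correlation), the clock list (-0.47, 0.00696 and 0.0521) and the phosphate list (0.60, 0.00118 and 0.0693) were called as in the wild type, on the same side. Besides the salicylic acid, jasmonate and superoxide dismutase lists, 6 lists were not called in pad4: those of ethylene, auxin, cytokinin, gibberellin, camalexin and root markers (camera adjusted p = 0.0962 to 0.907). The seed storage albumin gene SESA4 (AT4G27170) stood at 32.8, 44.2 and 36.8 FPKM in the pad4 libraries labelled -Fe and was listed at 0 in the other 9. Limma called 11572 loci in pad4, 5311 higher and 6261 lower in libraries labelled -Fe, of which 2618 differed by at least 1 log2 unit (1183 higher and 1435 lower). Here too the larger side turned after quantile normalization (5924 higher and 5520 lower).

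Both genotypes shared much of the response to the Fe label. Of the called loci, 7623 changed in the same direction in both, 3648 higher and 3975 lower in libraries labelled -Fe, where independent lists of these sizes would share 1338 and 1674. These calls use 1 spread per locus, fitted over all 12 libraries, so they are not fully independent. With only the compared groups in each fit, the shared loci were 3386 higher and 3672 lower, against 1199 and 1511. After quantile normalization the shared loci were 4108 higher and 3560 lower. The opposite direction was found for 374 loci. Fold changes of the 2 genotypes, which share no library, correlated across loci at r = 0.78 with a covariance of 0.471 (loci are not independent replicates).

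At +Fe, the genotypes differed in 1887 loci, 137 of them by 1 log2 unit or more. The largest rises in pad4 were those of HSP23.6 (1.90 log2 units, from 42.0 ± 5.75 to 160.3 ± 25.2 FPKM), HSFA7A (AT3G51910, a heat shock factor, 1.67), DIN2 (AT3G60140, a sugar starvation-induced glucosidase, 1.66), BAG6 (AT2G46240, a co-chaperone, 1.58), bZIP1 (AT5G49450, an energy-stress transcription factor, 1.57) and BT5 (AT4G37610, 1.57). The largest falls were those of PDF1.3 (-1.74), PCC1 (-1.69, from 102 ± 32.4 to 30.3 ± 5.04 FPKM), COR15B (AT2G42530, a cold-regulated chloroplast protein, -1.69), MDHAR (AT3G09940, an ascorbate-recycling reductase, -1.66), the immune receptor gene RLP23 (AT2G32680, -1.64) and TAT3 (AT2G24850, a jasmonate-responsive aminotransferase, -1.59). Limma adjusted p for these 12 genes ranged from 1.04e-06 for RLP23 and MDHAR to 0.00783 for PDF1.3.

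Defence lists were lower in pad4 at +Fe. In the salicylic acid list 0 of 33 tested members were called higher and 10 lower (14 called adjusted over the list alone, median -0.29, camera adjusted p = 6.62e-07), with DMR6 at -0.80. The mutated gene PAD4 is itself a member of this list and among the 10 lower. ICS1 had a difference of -0.39 (adjusted p = 0.0163), whose call ended without wild-type +Fe replicate 1 (log2 difference -0.41), 2 (-0.37) or 3 (-0.40) or pad4 +Fe replicate 1 (-0.39) or 3 (-0.36). PR1, EDS1 and NPR1 did not pass the test, with differences of 0.27, -0.18 and 0.02 (adjusted p = 0.283, 0.314 and 0.939), though PR1 (0.27) and EDS1 (-0.18) did with the replicate number as a block in the 9 libraries other than pad4 -Fe. In the jasmonate list 0 of 27 tested members were called higher and 10 lower (15 called adjusted over the list alone, median -0.22, camera adjusted p = 2.39e-07), with ORA59 (AT1G06160, a regulator of defensins) and OPR3 (AT2G06050, a synthesis enzyme) at -0.73 and -0.38. The abscisic acid list was also lower, as 0 of 16 tested members were called higher and 5 lower (6 called adjusted over the list alone, median -0.27, camera adjusted p = 1.79e-06), with COR15A, RD22 (AT5G25610) and the transcription factor gene HB7 (AT2G46680) at -1.25, -0.56 and -0.52. Phenylpropanoid genes were lower as a group: 0 of 17 tested members were called higher and 15 lower (17 called adjusted over the list alone, median -0.59, camera adjusted p = 3.75e-18). FLS1 (AT5G08640), F3H and DFR had differences of -0.93, -0.84 and -0.71. In the camalexin list 0 of 6 tested members were called higher and 3 lower (3 called adjusted over the list alone, median -0.26, camera adjusted p = 0.0163, 0.0693 with an estimated correlation), with the immune kinase gene FRK1 (AT2G19190) and the camalexin synthesis gene PAD3 (AT3G26830) at -0.78 and -0.50. The locus that merges GSTF6 and GSTF7 was also called (-0.81), but not without wild-type +Fe replicate 1 (-0.74).

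Other lists at +Fe moved either way. Of the cytokinin genes 4 of 13 tested members were called higher and 0 lower (7 called adjusted over the list alone, median 0.46, camera adjusted p = 0.00229, 0.0879 with an estimated correlation): the response regulator genes ARR6 (AT5G62920), ARR7 (AT1G19050) and ARR4 (AT1G10470) rose by 0.72, 0.83 and 0.50. Of the heat shock genes 8 of 10 tested members were called higher and 0 lower (9 called adjusted over the list alone, median 0.72, camera adjusted p = 3.9e-10, 0.0781 with an estimated correlation), with the chaperone gene HSP101 (AT1G74310) and the regulator gene HSFA2 (AT2G26150) up by 1.35 and 0.98. Of the photosynthesis genes 8 of 27 tested members were called higher and 1 lower (14 called adjusted over the list alone, median 0.21, camera adjusted p = 2.04e-05, 0.138 with an estimated correlation). LHCB4.2 (AT3G08940) and PORB (AT4G27440) rose by 0.92 and 0.65, and the chloroplast regulator gene GLK1 (AT2G20570) had a difference of -0.70. In the Fe acquisition list 0 of 10 tested members were called higher and 4 lower (5 called adjusted over the list alone, median -0.28, camera adjusted p = 0.002, 0.072 with an estimated correlation). FRD3, the coumarin synthesis gene F6'H1 and MYB72 had differences of -0.64, -0.63 and -0.51. The F6'H1 call ended without wild-type +Fe replicate 1 (-0.60) or pad4 +Fe replicate 2 (-0.55). The MYB72 call was lost with a pseudocount of 0.1 (-0.53). Among the Fe-deficiency regulators 1 of 29 tested members were called higher and 5 lower (7 called adjusted over the list alone), without a call of the list (camera adjusted p = 0.0772, but 0.0472 without wild-type +Fe replicate 2). The nicotianamine synthase genes NAS1 (AT5G04950) and NAS4 (AT1G56430) had differences of -0.71 and -0.62, and the reductase gene FRO7 (AT5G49740) rose by 0.45. bHLH38, bHLH39, bHLH100, bHLH101, FRO2, FIT, BTS and FER1 did not pass the test, with differences between -0.28 for bHLH38 and 0.27 for bHLH101, though bHLH101 did when only these 2 groups were fitted (0.27) and bHLH38 with the replicate block in the 9 libraries other than pad4 -Fe (-0.28). IRT1 stood at 5.76 ± 0.419 FPKM in the wild type and 4.61 ± 0.597 FPKM in pad4. The superoxide dismutase list had a median of -0.20 (camera adjusted p = 0.0447, 0.335 with an estimated correlation), and that call ended without wild-type +Fe replicate 1 (0.0793) or 3 (0.0652) or pad4 +Fe replicate 2 (0.104) or 3 (0.0571), without the low-value filter (0.0747), without the 4 libraries that stand apart (0.0727) and with the replicate block in 9 libraries (0.0818). Storage, ethylene, auxin, gibberellin, root, touch, clock and phosphate lists were not called (camera adjusted p = 0.0805 to 0.934), though the auxin list was without wild-type +Fe replicate 3 (0.0468). Limma called 1887 loci at +Fe, 745 higher and 1142 lower in pad4, of which 137 differed by at least 1 log2 unit (67 higher and 70 lower), or 230 with a pseudocount of 0.1 (104 and 126). The count was 1026 without wild-type +Fe replicate 1, 1048 without wild-type +Fe replicate 3, 1210 without pad4 +Fe replicate 2, 1203 without pad4 +Fe replicate 3, and 3151 without the 4 libraries that stand apart. With the replicate block in 9 libraries it was 5885, 2960 higher and 2925 lower in pad4. These last 2 alternatives were chosen after the data were seen.

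At -Fe, salicylic acid genes were lower in pad4. In that list 1 of 33 tested members were called higher and 24 lower (26 called adjusted over the list alone, median -0.78, camera adjusted p = 5.64e-13). The mutated gene PAD4 is itself among these 24. PR1 stood at 279.9 ± 48.6 FPKM in the wild type and 69.8 ± 5.04 FPKM in pad4 (log2 difference -1.98, SE 0.14, limma adjusted p = 1.38e-06). DMR6, NIMIN2 and the hydroxylase gene DLO1 (AT4G10500) had differences of -1.62, -1.58 and -1.92, ICS1 of -1.06 and EDS1 of -0.78, while NPR1 did not pass the test (-0.26, adjusted p = 0.228) except without the 4 libraries that stand apart (-0.22). In the camalexin list 1 of 6 tested members were called higher and 4 lower (5 called adjusted over the list alone, median -1.13, camera adjusted p = 0.00456, 0.0521 with an estimated correlation), with FRK1, CYP71A12 (AT2G30750) and PAD3 at -2.0, -1.60 and -1.37.

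Jasmonate defensins stood at higher levels in pad4 at -Fe. PDF1.2c (AT5G44430) and PDF1.3 rose by 4.55 and 4.43, PDF1.2c from 19.5 ± 6.5 to 494 ± 206 FPKM, and PR4 by 1.18. The PDF1.2 and PDF1.3 genes are near-identical copies between which reads can have been shared, so their single values are uncertain. The list as a whole was not called: 9 of 27 tested members were called higher and 6 lower (18 called adjusted over the list alone, median 0.17, camera adjusted p = 0.052), with a call without wild-type -Fe replicate 1 (0.0373) or pad4 -Fe replicate 3 (0.0135) or without the 4 libraries that stand apart (0.0185). In the abscisic acid list 0 of 16 tested members were called higher and 15 lower (15 called adjusted over the list alone, median -1.19, camera adjusted p = 1.67e-14). NCED3, HB7 and the phosphatase gene HAB1 (AT1G72770) had differences of -1.89, -1.85 and -1.04. In the auxin list 2 of 20 tested members were called higher and 10 lower (12 called adjusted over the list alone, median -0.36, camera adjusted p = 0.000553), with GH3.3, GH3.5 (AT4G27260) and IAA5 (AT1G15580) at -1.67, -1.70 and -1.32. Among the phenylpropanoid genes 0 of 17 tested members were called higher and 10 lower (10 called adjusted over the list alone, median -0.51, camera adjusted p = 1.11e-05, 0.0685 with an estimated correlation), with FLS1, PAP2 (AT1G66390) and PAL1 (AT2G37040, the entry enzyme) at -1.10, -1.90 and -1.02.

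The largest falls in pad4 at -Fe were all in heat shock protein genes. HSP21 stood at 209 ± 24.2 FPKM in the wild type and 0.0562 ± 0.0488 FPKM in pad4 (log2 difference -7.63, limma adjusted p = 4.56e-11), and ATHSP22.0, HSP17.6C, HSP18.2, HSP23.6 and HSP17.4 had differences of -7.47, -7.46, -6.42, -6.27 and -5.83. In the heat shock list 1 of 10 tested members were called higher and 9 lower (10 called adjusted over the list alone, median -5.60, camera adjusted p = 9.5e-13, 0.0582 with an estimated correlation). The member called higher was the regulator gene HSFA2. Among the largest rises, 4 were seed storage protein genes. CRA1 (AT5G44120, a cruciferin) rose from 0.0755 ± 0.0742 to 22.9 ± 3.45 FPKM. SESA4, SESA2 (AT4G27150) and CRU3 (AT4G28520) were listed at 0 in the 3 wild-type libraries labelled -Fe and stood in the pad4 ones at 32.8 to 44.2, 21.1 to 25.7 and 17.2 to 20.6 FPKM.

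Root markers and photosynthesis genes were both on the higher side in pad4 at -Fe. In the root list 2 of 6 tested members were called higher and 0 lower (2 called adjusted over the list alone, median 0.37, camera adjusted p = 0.0208, 0.0758 with an estimated correlation), and in the photosynthesis list 11 of 27 tested members were called higher and 1 lower (13 called adjusted over the list alone, median 0.32, 0.20 after quantile normalization, camera adjusted p = 0.000753, 0.236 with an estimated correlation). No Fe list was called. Among the Fe acquisition genes 0 of 10 tested members were called higher and 3 lower (3 called adjusted over the list alone, median -0.14, camera adjusted p = 0.0962): F6'H1 (AT3G13610, of coumarin synthesis), FIT and the proton pump gene AHA2 (AT4G30190) had differences of -1.02, -0.83 and -0.34. Among the Fe-deficiency regulators 3 of 29 tested members were called higher and 2 lower (4 called adjusted over the list alone, camera adjusted p = 0.76), with FRO7 and bHLH121 (AT3G19860) up by 1.12 and 0.50 and BTSL2 (AT1G18910) at -0.41. BTS had a difference of -0.22 (adjusted p = 0.0178), which lost its call without wild-type -Fe replicate 1 (log2 difference -0.19) or pad4 -Fe replicate 1 (-0.17) and when only these 2 groups were fitted. bHLH38, bHLH39, bHLH100, bHLH101, FRO2 and FER1 did not pass the test (0.07, 0.12, -0.18, -0.01, -0.17 and -0.08). The 4 bHLH genes lay at 0.666 FPKM or less in every library labelled -Fe, where the added 1 hides most of a difference. For these 4 genes the test cannot tell whether the genotypes differ at -Fe. Storage, superoxide dismutase, ethylene, cytokinin, gibberellin, touch, clock and phosphate lists were not called either (camera adjusted p = 0.123 to 0.904), though the touch list was without the 4 libraries that stand apart (0.0343). Limma called 5631 loci at -Fe, 2726 higher and 2905 lower in pad4, of which 765 differed by at least 1 log2 unit (223 higher and 542 lower), or 1079 with a pseudocount of 0.1 (339 and 740). After quantile normalization the larger side turned (2910 higher and 2803 lower). Genotype calls at the 2 supplies, which share no library, coincided in the same direction for 952 loci, 360 higher and 592 lower in pad4, where independent lists would share 101 and 164, and went opposite ways for 269. Both sets of calls use 1 spread per locus, fitted over all 12 libraries, so the 101 and 164 can be too low. The overlap with each supply fitted alone was not examined.

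The interaction asked whether the effect of the Fe label differed between the genotypes. Values are the effect in pad4 minus that in the wild type. The largest positive values belonged to defensins and seed storage genes: PDF1.3 (6.17, SE 0.48, limma adjusted p = 7.56e-06), PDF1.2c (5.88), PDF1.2a (AT5G44420, chromosome 5, 17907069 to 17907598, 5.65), CRA1 (4.69), PDF1.2b (AT2G26020, 4.48) and SESA4, which was listed at 0 in 3 of the groups. PDF1.2a went from 101 ± 27.8 to 31.8 ± 10.4 FPKM in the wild type and from 34.3 ± 10.48 to 566 ± 192 FPKM in pad4. The most negative values belonged to heat shock protein genes: ATHSP22.0 (-8.30, SE 0.14, adjusted p = 6.73e-11), HSP23.6 (-8.17), HSP17.6C (-7.95), HSP21 (-7.71), HSP18.2 (-6.99) and HSP17.4 (-6.95). In the heat shock list 0 of 10 tested members were called higher and 10 lower (10 called adjusted over the list alone, median -6.47, camera adjusted p = 1.89e-21), with HSP17.6II at -5.98.

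Hormone lists separated in the interaction. In the salicylic acid list 3 of 33 tested members were called higher and 17 lower (22 called adjusted over the list alone, median -0.47, camera adjusted p = 6.62e-07), with PR1 at -2.24 (SE 0.20, limma adjusted p = 2.2e-05), DLO1 at -1.85, NIMIN2 at -1.18, ICS1 at -0.66 and EDS1 at -0.60. NPR1 and PAD4 itself did not pass the test (-0.28 and -0.07, adjusted p = 0.412 and 0.773). In the abscisic acid list 1 of 16 tested members were called higher and 12 lower (13 called adjusted over the list alone, median -0.92, camera adjusted p = 7.22e-10), with the dehydrin gene ERD10 (AT1G20450), NCED3 and HB7 at -1.95, -1.70 and -1.34. In the auxin list 1 of 20 tested members were called higher and 11 lower (14 called adjusted over the list alone, median -0.55, camera adjusted p = 5.52e-06), with IAA5, GH3.5 and GH3.3 at -2.05, -1.71 and -1.53. The jasmonate list took positive values, as 14 of 27 tested members were called higher and 0 lower (16 called adjusted over the list alone, median 0.39, camera adjusted p = 6.54e-06, 0.0619 with an estimated correlation). In the root list 2 of 6 tested members were called higher and 0 lower (3 called adjusted over the list alone, median 0.61, camera adjusted p = 0.00536, 0.0521 with an estimated correlation), with the nitrate transporter gene NRT2.1 (AT1G08090) at 1.19. The other member called, PRP3, lost its call with a pseudocount of 0.1 and without the 4 libraries that stand apart.

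Of all 20173 loci tested, 2957 passed the interaction test. So did 1 of 8 Fe storage genes and 1 of 10 Fe acquisition genes tested. Among the Fe-deficiency regulators 4 of 29 tested members were called higher and 0 lower (3 called adjusted over the list alone, median 0.16, camera adjusted p = 0.0476, 0.343 with an estimated correlation). This call ended without wild-type +Fe replicate 1 (0.0616) or 3 (0.0618), wild-type -Fe replicate 2 (0.0743), pad4 +Fe replicate 2 (0.0878) or pad4 -Fe replicate 2 (0.124). The values of bHLH38, bHLH39, bHLH100 and bHLH101 were 0.36, 0.16, -0.33 and -0.28, and those of FRO2, FIT, BTS and FER1 -0.20, -0.66, -0.21 and -0.07, none of which passed the test, though FIT did without wild-type +Fe replicate 2 (-0.81) and bHLH38 without the 4 libraries that stand apart (0.42). IMA1 did, at 0.86 (adjusted p = 0.0492), a call near the threshold whose dependence on single libraries was not examined. The 4 bHLH genes lay at 0.666 FPKM or less in every library labelled -Fe. A genotype difference there would hardly enter their interaction values, which therefore cannot exclude one. In the camalexin list 0 of 6 tested members were called higher and 3 lower (4 called adjusted over the list alone, median -0.48, camera adjusted p = 0.0286, 0.0869 with an estimated correlation). The other 11 lists were not called (camera adjusted p = 0.0878 to 0.904), though the superoxide dismutase list was without pad4 -Fe replicate 3 (0.0388) or the 4 libraries that stand apart (0.0486), and so were the cytokinin (0.0242) and touch (0.0185) lists without these 4. Limma called 2957 loci for the interaction, 1427 positive and 1530 negative, of which 703 reached 1 log2 unit (293 and 410). Of the 2957, the Fe label had called effects of the same direction in both genotypes for 1081 (larger in pad4 for 587 and in the wild type for 494), of opposite directions for 374, in the wild type alone for 674, in pad4 alone for 820 and in neither for 8.

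**Figure D3:**
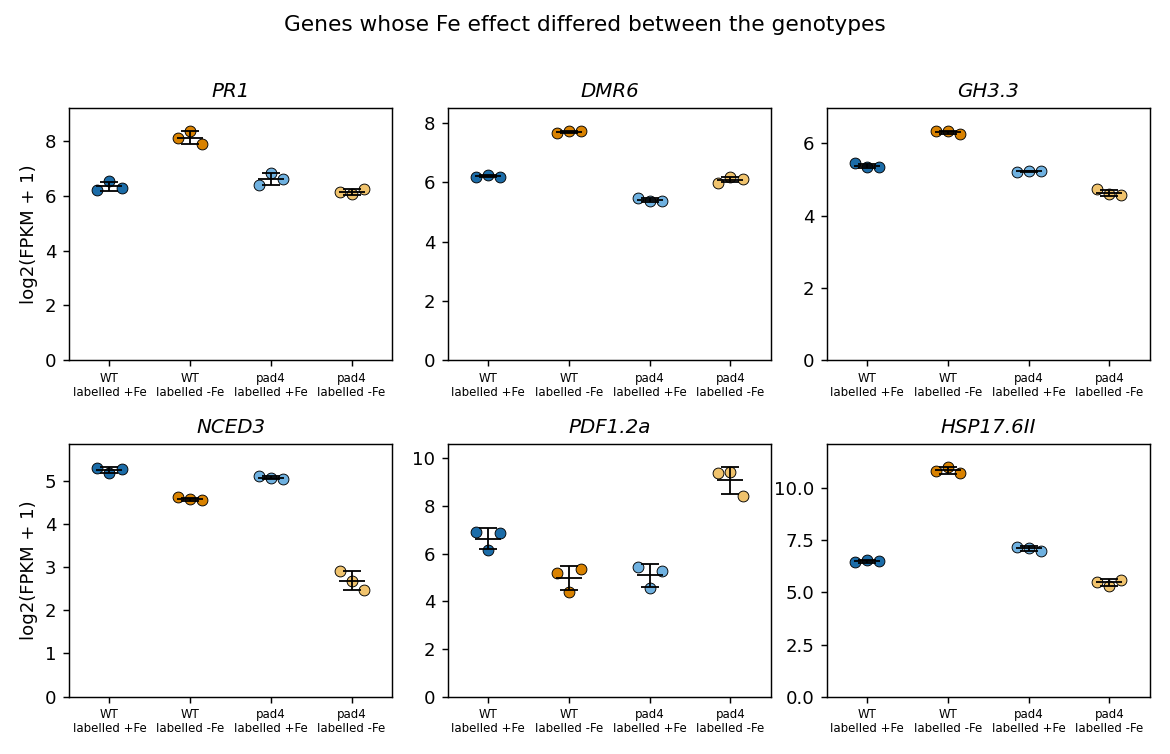
Log2(FPKM + 1) of 6 genes (vertical axes, from 0) in the 4 groups, with points for libraries and bars for the mean and SD (n = 3). PR1, DMR6, GH3.3 and HSP17.6II are highest in the wild-type libraries labelled -Fe, NCED3 is lowest and PDF1.2a highest in the pad4 libraries labelled -Fe.

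**Figure D4:**
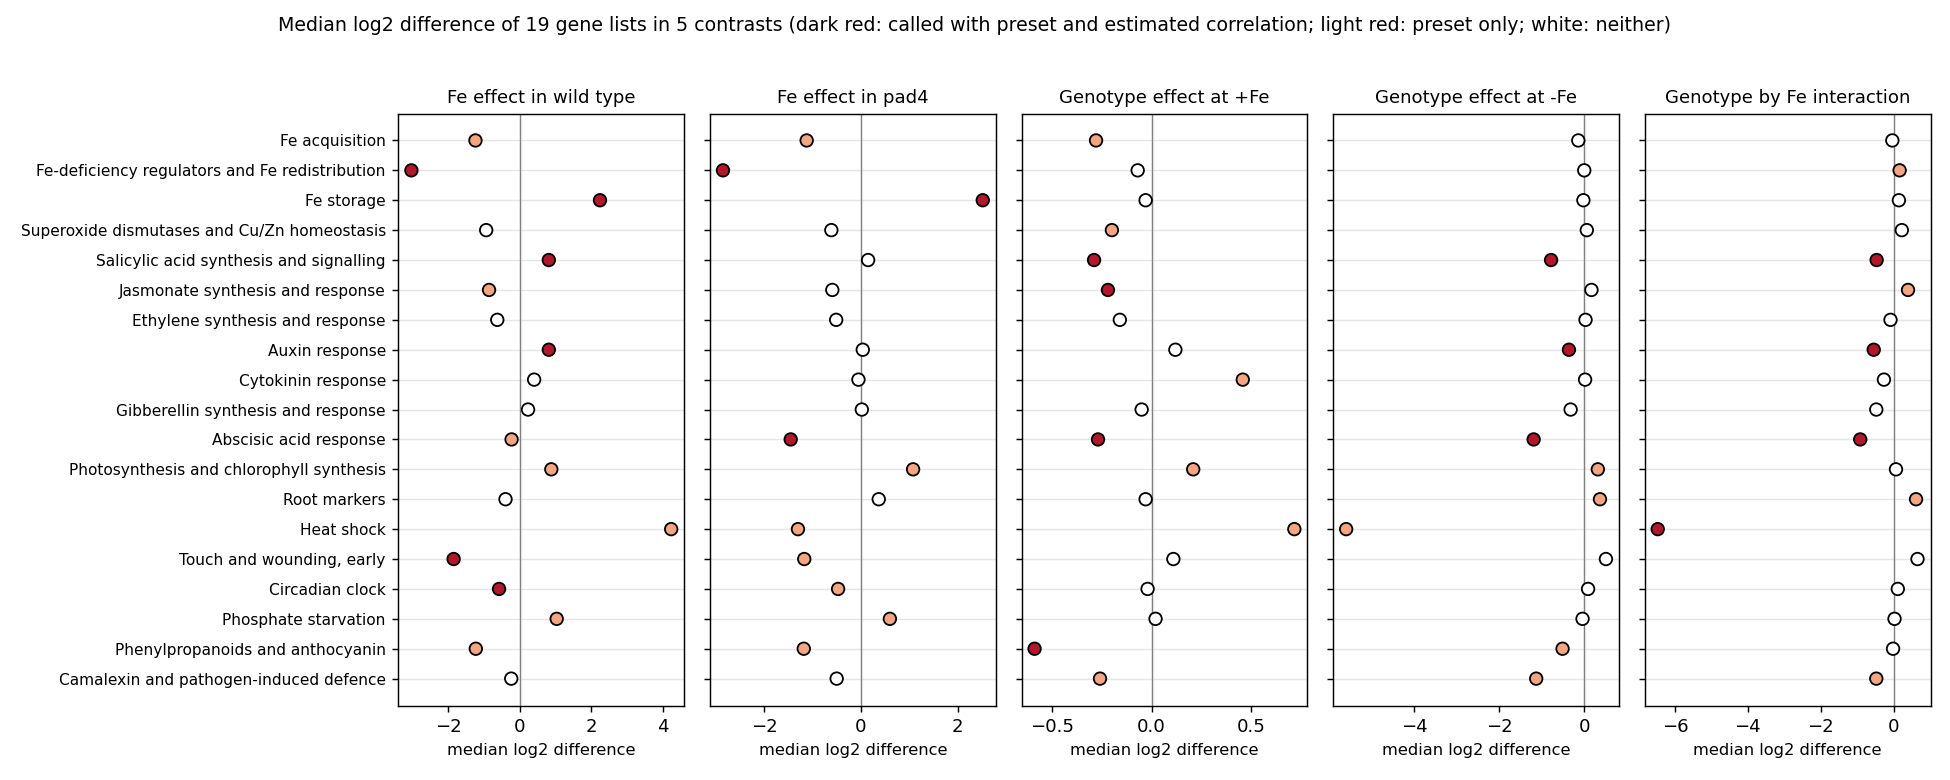
Median log2 difference (horizontal axes, which differ in range) of 19 gene lists (vertical) in the 5 contrasts. Each point is a list: dark red lists were called by camera with the preset and the estimated correlation, light red lists with the preset correlation only, and white lists with neither. The heat shock list lies at 4.23 for the Fe label in the wild type and at -6.47 for the interaction, and the salicylic acid list at -0.78 for genotype at -Fe.

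Calls of the authors were set beside these. The smallest log2 fold among the loci they called was 1.0 in size in each comparison, whereas the calls here had no size limit. The authors' deposited table for the wild type called 3232 loci between the Fe labels (1593 higher and 1639 lower in -Fe), that for pad4 3519 (1680 and 1839), that for genotype at +Fe 271 (125 higher and 146 lower in pad4) and that for genotype at -Fe 1047 (311 and 736). Of the loci called in the authors' deposited tables that were also tested here, 3015 of 3055, 3330 of 3352, 213 of 248 and 988 of 998 were called here in the same direction, and none in the opposite one. Of the loci called here at 1 log2 unit or more, the authors called 2180 of 2364 in the wild type and 2396 of 2618 in pad4 between the Fe labels. For genotype they called 121 of 137 at +Fe and 698 of 765 at -Fe. The authors' deposited table gave PR1 log2 folds of 1.78 in the wild type and -0.47 in pad4, and -2.0 between genotypes at -Fe. The authors did not call the fold in pad4, which had a q-value of 0.0012 in the authors' deposited table but was smaller than any fold they called. In the authors' deposited table bHLH100 had log2 folds of -10.77 and -11.42 between the Fe labels, both called and with the same sign as here. The authors did not call bHLH38, bHLH39 or bHLH101 in either genotype, with log2 folds of -9.35 to -12.44 and q-values of 0.0803 to 0.222 in the authors' deposited table.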

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

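Of the tests in this part, the reading of an inverse response of the Fe markers and, for the heat shock genes, the tests of 1 library and of scaling were chosen after the result was seen. The 67 genes below are listed because the effect of the Fe label differed between the genotypes by the test of the difference itself. Values are the log2 effect in pad4 minus that in the wild type.

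Among the heat shock genes the differences were -8.30 for ATHSP22.0, -8.17 for HSP23.6, -7.95 for HSP17.6C, -7.71 for HSP21, -6.99 for HSP18.2, -6.95 for HSP17.4, -5.98 for HSP17.6II, -2.28 for HSP101, -1.83 for BAG6 and -0.46 for HSFA2. Among Fe and metal genes they were 0.86 for IMA1, 0.45 for FRD3, 0.48 for CCH, 0.77 for NAS1, 0.48 for NAS4 and 0.67 for FRO7. Among genes of salicylic acid and defence they were -2.24 for PR1, -1.85 for DLO1, -1.18 for NIMIN2, -1.12 for FMO1, -0.82 for DMR6, -0.66 for ICS1, -0.60 for EDS1, -1.10 for UGT76B1, 1.02 for PCC1, -0.96 for RLP23, -1.22 for FRK1, -0.87 for PAD3 and -1.59 for CYP71A12.

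In the jasmonate group the differences were 6.17 for PDF1.3, 5.88 for PDF1.2c, 5.65 for PDF1.2a, 4.48 for PDF1.2b, 1.39 for PR4, 1.01 for CHIB, 0.95 for LOX4, 0.81 for ORA59, 0.70 for AOS and 0.34 for LOX2. Abscisic acid and cold genes stood at -1.95 for ERD10, -1.70 for NCED3, -1.34 for HB7, -1.11 for ABI2, -0.89 for HAB1, 0.42 for RD22 and 1.22 for COR15B. Auxin and cytokinin genes stood at -2.05 for IAA5, -1.71 for GH3.5, -1.53 for GH3.3, -0.95 for GH3.6, -0.49 for PIN3, -0.81 for ARR7 and -0.47 for ARR4. Stress and clock regulators stood at 1.09 for ZAT10, 0.73 for ZAT12, 0.90 for ELF4 and 0.48 for PRR9. The flavonoid genes were at 0.79 for UF3GT, 0.68 for DFR, 0.43 for F3H and -0.94 for PAP2. The remaining genes were at 4.69 for CRA1, 1.19 for NRT2.1, 0.61 for MDHAR, -0.81 for PHT1;4, -0.59 for BT5 and -1.61 for DIN2.

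Most Fe-deficiency markers were higher in the libraries labelled +Fe, but 2 of 29 regulators in the wild type, 4 of 29 in pad4 and 2 of 10 acquisition genes in each genotype were called the other way, FIT among them (1.2 in the wild type and 0.54 in pad4). Scaling between libraries is argued against, since the median fall of the 4 bHLH genes was still -8.24 in the wild type and -7.94 in pad4 after quantile normalization. An exchange of the Fe labels in both genotypes is a candidate explanation. Its test took 8 markers whose values had not been looked at. Their median log2 differences were -3.76 in the wild type and -3.50 in pad4, below the -0.5 set in advance. An inverse response to a correctly labelled supply would lower such markers too, so their fall does not favour an exchange. The 2 explanations cannot be told apart, because the files hold no measure of Fe. The median of 2.24 of the Fe storage list in the wild type is itself a transcript value. The labels were left as given, although the sample titles mark libraries labelled -Fe with CK, a usual code for a control, and those labelled +Fe with FE.

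At -Fe, salicylic acid markers were lower and jasmonate defensins higher in pad4. A single library is argued against, since leaving out any 1 library moved PR1 or PDF1.2a by at most 0.32 log2 units and ended neither call. A different time of harvest is a candidate explanation: the size of the genotype difference over the clock genes lay at percentile 98.9 of 10000 random lists matched on expression, above the 95 set in advance, although the clock list itself was not called at -Fe (camera adjusted p = 0.495). The percentile ignores sign, and 4 clock genes were called higher and 2 lower (median 0.09). The random lists were not matched on shared regulation, and morning and evening genes were not compared for this contrast. The percentile therefore does not single out time of harvest. Tissue composition cannot be told apart, since the root marker median of 0.37 lay between the bounds set in advance, although the photosynthesis list, which a larger root share should lower, had a median of 0.32. Exposure of the wild-type seedlings labelled -Fe to heat, weighed below for the heat shock genes, falls on this same contrast. The heat shock list had a median of -5.60 there, and whether heat moved the salicylic acid and jasmonate genes was not tested. Seed material in the pad4 harvest was not tested (SESA4 at 32.8 to 44.2 FPKM in pad4 and listed at 0 in the wild type), and the genotype itself stays open as the biological explanation.

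The median of the heat shock list was higher in the 3 wild-type libraries labelled -Fe than in the other 9. Of its 10 members, HSFA2 alone was called higher in pad4 than in the wild type at -Fe. A single library is argued against, as the lowest of the 3 list medians exceeded the highest of the others by 2.62 (9.74 against 7.13), and so is scaling, as the genotype difference was -5.47 after quantile normalization. Exposure of the wild-type seedlings labelled -Fe to heat is a candidate explanation, with a median of -1.51 over 12 heat-induced genes outside the list. That evidence is mixed: 7 of the 12 were called lower in pad4 at -Fe, but 4 were called higher, namely MBF1C (0.73), HSFA7A (1.31), HSFB2A (0.83) and DREB2A (1.53). A response of the wild type to the Fe supply sits on the same 3 libraries and stays open.

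For the number of called loci, the 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real value was 10475 for the Fe effect in the wild type (highest other split 1), 11572 in pad4 (1), 1887 for genotype at +Fe (1) and 5631 for genotype at -Fe (2). In the 2 comparisons whose same-numbered libraries correlate, 3 other splits also part all 3 pairs, with at most 1 locus for the Fe effect in the wild type and 0 for genotype at +Fe. The other 6 splits part only 1 pair and gave at most 0 and 1. For the interaction, 100 splits were drawn, and the real one, with 2957 loci, was the only one to reach its count (share 0.01). The 6 next, at 1501 to 2678, all kept the genotypes apart at -Fe, and the 93 others gave at most 31. The count thus follows which libraries were mixed, and does not decide whether chance can be excluded.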

How the results depend on the processing

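Fits without the 4 libraries that stand apart, without loci with a 0 beside a high value, and with the replicate block in 9 libraries were chosen after the results were seen. With a threshold of 1 log2 unit the counts of called loci were 2364 of 10475 (Fe effect in the wild type), 2618 of 11572 (Fe effect in pad4), 137 of 1887 (genotype at +Fe), 765 of 5631 (genotype at -Fe) and 703 of 2957 (interaction). Those above the threshold with a pseudocount of 0.1 were 3214, 3601, 230, 1079 and 964. The genotype count at +Fe was also 1026 to 1612 without 1 library (lowest without wild-type +Fe replicate 1) and 3151 without the 4 libraries that stand apart, for which the cause was not tested. With the replicate block in 9 libraries it was 5885, and that of the Fe effect in the wild type 13366. That block was run for 104 results of named genes and 38 list tests. Among these it gave calls to 5 results of named genes, ended that of the superoxide dismutase list at +Fe, and changed no other call. The other counts stayed within 1.5 times their value under every setting run besides the threshold. Of 95 list tests, 49 were called with the preset correlation, 20 with an estimated correlation and 77 with fry. The auxin list in pad4 turned to lower libraries labelled -Fe with fry (adjusted p = 0.0366, against 0.907 and the higher side with camera); the cause was not tested, and its camera p is not a call. Of 234 results of named genes, 7 lost and 3 gained a call without 1 library. None that was called in the main fit or in the other setting changed direction between them. The direction of results called in neither was not compared. Quantile normalization, the fit of only the compared groups and the pseudocount of 0.1 changed the calls of 1, 3 and 2 of them. Without the 4 libraries, 1 lost and 3 gained a call. Of the lists, 3 lost and 4 gained a call without 1 library, 1 lost and 1 gained it without the low-value filter, and 1 lost and 5 gained it without the 4 libraries: jasmonate (0.0185) and touch (0.0343) at -Fe, and superoxide dismutase (0.0486), cytokinin (0.0242) and touch (0.0185) for the interaction. With the replicate block in all 12 libraries the counts were 10538, 11662, 1870, 5638 and 2929, and no named gene or list call changed. The absolute depth is unknown, so how it limits low genes could not be computed.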

Other observations

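In this part, the seed storage genes, the annotation families and the test of gene length in the 3 libraries numbered 2 were chosen after their values were seen. Of 12 seed storage protein and oil body genes, 7 were measured at over 5 FPKM only in the pad4 libraries labelled -Fe. SESA4 stood at 32.8, 44.2 and 36.8 FPKM there and was listed at 0 in the other 9 libraries, and SESA3 (AT4G27160) stood at 15.1, 23.7 and 16.4 FPKM and was likewise listed at 0 in the other 9. The cruciferin genes CRA1, CRU2 (AT1G03880) and CRU3 stood at 19.6 to 26.5, 10.1 to 12.6 and 17.2 to 20.6 FPKM, and at most at 0.391, 0.0383 and 0.0390 FPKM elsewhere. The oleosin genes OLEO1 (AT4G25140) and OLEO2 (AT5G40420) stood at 15.6, 13.2 and 19.4 and at 10.48, 8.70 and 11.1 FPKM. The other 5 differed. SESA2 and SESA5 (AT5G54740) were also measured in the 6 libraries labelled +Fe, at 10.2 to 13.6 and 3.38 to 5.32 FPKM, and listed at 0 in wild-type -Fe libraries. OLEO4 (AT3G27660) stood at 7.25 to 7.67 FPKM in wild-type -Fe libraries and 1.72 to 3.87 FPKM in those labelled +Fe. OLEO3 (AT5G51210) reached at most 3.08 FPKM and SESA1 (AT4G27140) at most 1.02 FPKM in any library. Reads can have been shared between similar copies within a family, such as the SESA genes, so single values within a family are uncertain.

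Of 141 annotation families tested with camera, those called higher in libraries labelled -Fe in both genotypes were the chlorophyll-binding, core histone, cyclin, kinesin, tubulin, peroxidase, plastocyanin-like and aminotransferase families. With an estimated correlation none was called. In the wild type 23 of 36 cyclin loci were called higher and 3 lower (median 0.67, camera adjusted p = 0.00162, 0.31 with an estimated correlation), and of 23 core histone loci 17 higher and 1 lower (0.59, 0.000448 and 0.398). In pad4 22 cyclin loci were called higher and 3 lower (0.71, 0.000421 and 0.31), and 18 histone loci higher and 1 lower (0.67, 0.000265 and 0.372). Of 55 protein phosphatase 2C loci, 7 were called higher and 34 lower in pad4 (-0.41, 0.00202 and 0.561).

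In each group, 1 library deviates along an axis shared with the other 3 (correlations 0.41 to 0.51). Gene length is argued against for the 3 of them numbered 2 (Spearman rho 0.04, 0.04 and 0.01). For pad4 -Fe replicate 3 it cannot be told apart (0.16, between the bounds set in advance), and the largest rho, -0.33, was in pad4 -Fe replicate 1, which does not stand apart. Time of harvest by clock genes (differences 0.16 to 0.25) and heat or handling (medians 0.15 to 0.26) had 1 sign in all 4 libraries but lay between the bounds, so they cannot be told apart as explanations. No biological explanation was tested for this axis, since the labels give no further group.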
